A study of Rattus norvegicus with 15 samples.

How the data were processed

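Right lungs of male Wistar rats were measured on a one-colour (Cy3) Agilent whole-genome rat array, with 60 arrays in 15 groups of 4: vehicle (BSA), CNT-1 or CNT-2 on day 1, 3, 7, 30 or 90. The labels do not number the rats, so each of the 4 scanner files of a group was taken as 1 rat. RNA came from lungs perfused with saline and was amplified and labelled with a linear amplification kit, per the labels' protocols.

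The deposited scanner files give a spot intensity that Agilent Feature Extraction 10.7.3.1 background-subtracted and detrended within each array, with no scaling between arrays, per the file headers. They also give the mean spot intensity and the local background as scanned. The authors deposited 1 table of log2 values per array as well, and no label says how these were made. Checked against the scanner files, each table matched the log2 processed intensity minus the array's 75th percentile, minus the median of the day's 4 vehicle arrays for each probe. The lowest correlation across probes over the 60 arrays was 0.9994, the slopes ran from 0.991 to 1.004 and the largest median difference was 0.0535. The deposited series table holds log2 values that differed from the mean of a group's 4 tables by at most 0.00051. Its column medians for vehicle, CNT-1 and CNT-2 were 0.001, −0.055 and 0.76 on day 1, 0.0004, 0.1198 and 0.0905 on day 3, and −0.0017, −0.0549 and 0.0808 on day 7. They were 0.0008, 0.0662 and 0.0541 on day 30 and −0.0002, 0.0218 and 0.0304 on day 90.

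All values reported were computed from the processed intensity in the scanner files. It was put on the log2 scale, the spots of a probe were averaged without those that Feature Extraction marks as non-uniform or as deviating from their repeats (unless all were marked), and the 75th percentile of the array's 43379 non-control spots was subtracted. Of the 41012 non-control probes, 22495 received a gene name. The RefSeq gene table of assembly GRCr8 named 17512 by accession, 3095 by current symbol and 553 by synonym, and 1335 kept the name in the files. The other 18517 had no gene name and were left out. Coordinates are those of the probes in the files, on build rn4. Each gene was represented by its probe with the highest mean over the 60 arrays. It was tested if Feature Extraction marked that probe as well above background on all 4 arrays of at least 1 group, which held for 13559 of 17336 genes.

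Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over the 60 arrays (45 residual and 2.61 prior degrees of freedom), and tested with limma's moderated statistic, two-sided. The 15 contrasts by day set each material against vehicle and CNT-2 against CNT-1. A further 2 contrasts, the interactions, are the effect of a material on day 90 minus that on day 1. Adjusted p values are Benjamini-Hochberg values within a contrast, and genes under 0.05 were counted. Where a probe was well above background on no array of 1 of the groups, the fold is a bound. It was computed with that group's value on each array taken as the higher of its own and the lowest signal well above background, and is printed as at least that fold. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.

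The genes named were chosen by rule. For each contrast with vehicle they are the 5 largest increases and 3 largest decreases among genes with an adjusted p under 0.05, with every array of 1 group beyond every array of the other and well above background on all 4 arrays of the higher group. For each contrast of CNT-2 with CNT-1 they are the 4 largest each way under the same conditions, and for each interaction the 4 largest each way without the condition on separate arrays. For each gene list and material they are up to 4 members with the smallest adjusted p in any of the material's 5 contrasts with vehicle. The 724 tested genes with unnamed locus symbols were skipped. The rule gave 444 pairs of gene and contrast. In 83 of them the gene had over 1 probe that passed the filter, and in 11 of these a probe changed in the other direction. Values of a named gene in further contrasts are given for comparison.

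Gene lists were 43 in number, of cell markers, immune and stress responses, matrix, metabolism and neighbouring tissues, with 703 genes, of which 606 were measured. Many are also expressed by other lung cells and some belong to several lists, so the shift of a list does not count cells. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 215 tests of each kind of contrast. Camera called 134 tests for CNT-1, 113 for CNT-2 and 63 for CNT-2 against CNT-1, of 645 in all. With the correlation estimated from the data, 50, 30 and 17 of these held. The median, the mean and the test of a list differed in sign in 0 of the 310 called tests. The other tests were not checked for this. The correlation of the changes of both materials was set against 100 simulated data sets of unchanged groups that share vehicle arrays, and computed again with the vehicle arrays split.

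The fit was tested on simulated data with the genes' own means and spreads, in which 200 of 13559 genes were changed in CNT-1 against vehicle on day 7. A list of 20 further genes was raised there by 0.6 on the log2 scale. These data held no effect of a slide, so the shares that follow do not cover one. Of the genes changed by 0.5, 1 and 2 on the log2 scale, 41.8%, 74.6% and 98.5% were called, 0 of the changed genes were called in the wrong direction and 3.7% of the calls were unchanged genes.

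The groups, tests, gene lists, rule for named genes and most alternatives were set before the data were examined. Alternatives were normexp background correction of the scanned intensities (offset 50), quantile normalization, centring on the array median, no filter on dim probes, the mean of all probes, the authors' tables, a trended and robust spread, array weights, the arrays of the day alone, a replicate block, a change of at least 2-fold, an adjusted p under 0.01, an estimated correlation within lists and leaving out each array in turn. The fits without the day 1 arrays, without the CNT-2 day 1 arrays, and with day 3 in place of day 1 in the interactions were chosen after seeing the data. Slide as a block could not be fitted, because each group filled its own slide.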

Results

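Gene expression was measured in the right lungs of 60 male Wistar rats, with 1 one-colour array per lung, after a single instillation into the trachea. Each rat received 0.4 mL of bovine serum albumin (BSA, the vehicle) at 1.0 mg/mL, either alone or with CNT-1 or CNT-2 suspended in it, at 0.4 mg per rat. CNT-1 and CNT-2 are the labels' code names for single-wall carbon nanotubes. Lungs were taken 1, 3, 7, 30 and 90 days later from 4 rats per group, which made 15 groups. The comparisons ask which lung genes each material changed, whether the change lasted to day 90 and where the materials differed. In the group means, between 63.4% (CNT-1 day 3) and 68.6% (vehicle day 1) of the probes lay well above background, with 58.9% and 73.4% on the lowest and the highest array. The number of arrays limits the precision. The median SD of a gene between the lungs of a group was 0.17 on the log2 scale. Each group filled 1 slide of its own, so slide and group cannot be told apart in any comparison. The 15 slides were scanned on 9 days. CNT-1 and vehicle shared a scan day on days 1, 3, 30 and 90, CNT-2 and vehicle on day 90, and the 2 materials on days 7 and 90.

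The lungs of day 1 stood apart from all later ones. Over 13559 genes, principal component 1 held 47.1% of the variance and placed the CNT-2 day 1 lungs between −185.8 and −152.8, the CNT-1 day 1 lungs between −96.7 and −39.9 and the vehicle day 1 lungs between −33.8 and −17.9. The other groups had means from 17.4 to 27 there. Component 2 held 17.4% and separated vehicle from both materials on days 3 to 90. Signal differed most on day 1 too: the 75th percentile of an array was 8.49 ± 0.17 (log2 intensity, SD, n = 4) in CNT-2 day 1, 10.41 ± 0.74 in CNT-1 day 1, and between 9.70 and 10.39 in the mean of every other group. The mean correlation across genes between the arrays of a group, where genes are not independent replicates, was 0.9718 in CNT-1 day 1, 0.9869 in CNT-2 day 1 and 0.9925 or more elsewhere.

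**Figure D1:**
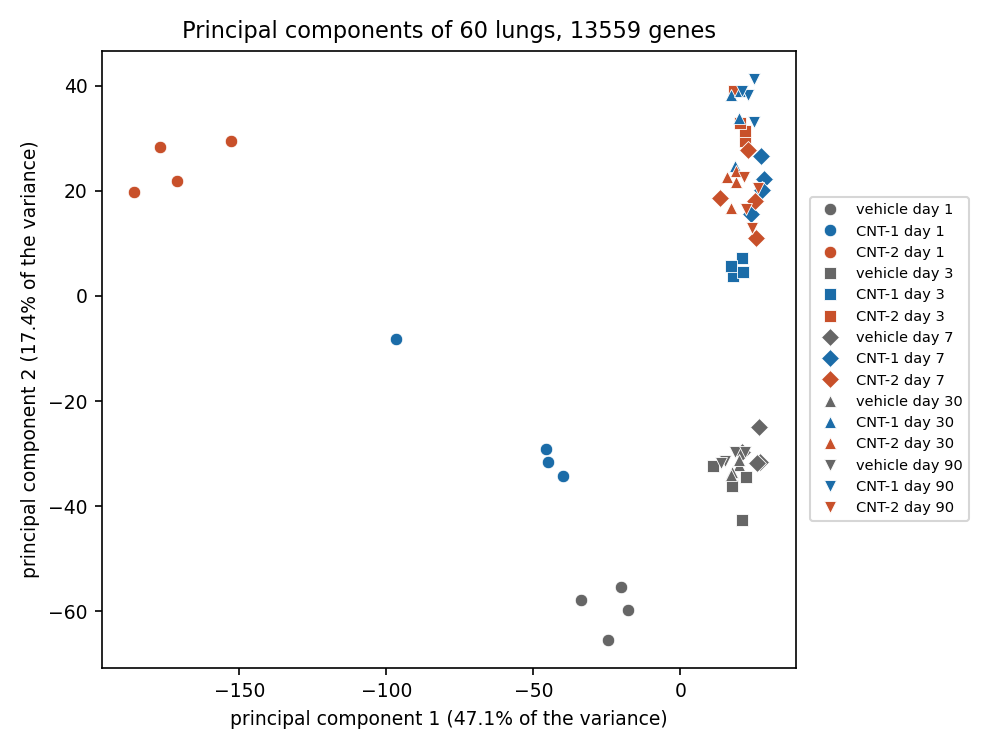
Each point is 1 lung, placed by its scores on principal components 1 (horizontal) and 2 (vertical) of the log2 intensities of 13559 genes, with colour for the material and shape for the day. The CNT-2 day 1 lungs lie between −185.8 and −152.8 on component 1, and the group means of days 3 to 90 between 17.4 and 27.

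CNT-1 against vehicle asks what CNT-1 did to the lung at each time. On day 1, Orm1, which encodes the acute-phase protein alpha-1-acid glycoprotein, rose by 6.14 ± 0.34 (log2 change ± SE; adjusted p = 3.41e-20; rn4 chromosome 5, 80326525 to 80326584). Il24, a cytokine of the IL-10 family, rose by 4.89 ± 0.30 (adjusted p = 1.23e-18), and Spp1, the gene of the secreted glycoprotein osteopontin, by 4.79 ± 0.32 (adjusted p = 1.47e-17; chromosome 14, 6422382 to 6422441). Each SE and p value of a gene, here and below, rests on a spread pooled over all groups. Arrays of day 1 varied more: Spp1 levels ran from 1.8 to 4.1 over the CNT-1 arrays, against 2.1 to 2.6 on day 3. With the spread of the day 1 arrays alone, 2639 genes passed on day 1 in place of 6681. The SE and p values of day 1 can thus overstate the precision. The change of Spp1 was 5.14 on day 3, 7.91 on day 7, 8.60 on day 30 and 8.80 on day 90 (447-fold; adjusted p = 6.89e-28). Mmp7, a secreted matrix metalloproteinase of epithelia, was 217-fold higher on day 7, at least 288-fold higher on day 30, and 164-fold higher on day 90. Mmp12, the macrophage elastase, was 79.4-fold higher on day 90 (6.31 ± 0.21; adjusted p = 1.63e-29). Cxcl11, a chemokine for activated T cells that interferons induce, was at least 87.2-, 69.9- and 93.2-fold higher on days 3, 7 and 30. Slc26a4, the anion exchanger pendrin of airway epithelium, rose by 5.59 ± 0.19 on day 3 and by 6.12 ± 0.19 on day 90 (adjusted p = 4.81e-30; chromosome 6, 49389243 to 49389302). Retnla, a marker of alternatively activated macrophages, rose by 6.22 ± 0.31 on day 30, and Lpo, which encodes the airway enzyme lactoperoxidase, was at least 153-fold higher on day 90 (adjusted p = 7.99e-26). Ccl12, a monocyte chemokine, rose by 5.39, 5.70 and 6.14 on days 3, 7 and 30.

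Fewer genes fell as far under CNT-1. Tac1, the precursor of the sensory neuropeptide substance P, fell by 2.73 ± 0.22 on day 3 (adjusted p = 2.11e-14; chromosome 4, 32657311 to 32657369) and by 2.48 ± 0.22 on day 30. Klk6, a secreted serine protease, fell by 2.42 ± 0.24 on day 30 and by 3.06 ± 0.24 on day 90 (adjusted p = 3.42e-15), when Acoxl, a relative of peroxisomal acyl-CoA oxidases, was at least 13.3-fold lower. On day 1 the largest falls were those of Cdc42ep3, a regulator of the actin cytoskeleton, by 3.65 ± 0.54, of the zinc finger gene Zfp608, by 3.36 ± 0.32, and of the deubiquitinase gene Otud1, by 3.26 ± 0.31. In Cdc42ep3 and Zfp608, 1 CNT-1 array lay far from the other 3, with an SD of 2.87 and 1.37 in that group. Without that array, array 1, the falls were smaller than that of Otud1: Cdc42ep3 fell by 2.21, Zfp608 fell by 2.68 and Otud1 fell by 2.94.

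Markers of neutrophils, the granulocytes that enter an inflamed lung early, were high from day 1 to day 90. Of the 13 measured, 13, 12, 12, 12 and 11 rose on days 1, 3, 7, 30 and 90, with the same numbers adjusted over the list alone, and the median change was 1.55, 1.91, 1.96, 1.77 and 1.5 (camera adjusted p between 6.96e-14 and 3.61e-08, and between 0.00231 and 0.00728 with an estimated correlation). S100a9, a subunit of the neutrophil protein calprotectin, rose by 4.21 ± 0.21 on day 30 (adjusted p = 5.18e-22), and Lcn2, which encodes a siderophore-binding granule protein, by 4.75 ± 0.18 on day 7. Il1r2, the decoy receptor of interleukin 1, rose by 3.74 ± 0.14 on day 3. Neutrophil chemokines and their receptors had a median of 2.39 on day 3 and of 1.31 on day 90, when 6 of 7 were higher and 1 lower (6 and 1 adjusted over the list alone). Cxcl2 rose by 3.39 ± 0.18 on day 3. Among 21 monocyte and lymphocyte chemokines, 15 were higher and 3 lower on day 90 (15 and 3 adjusted over the list alone; camera adjusted p = 2.28e-08, and 0.019 with an estimated correlation), and Ccl7 rose by 5.27 ± 0.18 (adjusted p = 1.22e-28). Of 17 inflammatory cytokines and regulators, 12 rose on each of days 3 to 90, with 12 adjusted over the list alone, and Il1rn, the interleukin 1 receptor antagonist, rose by 2.86 ± 0.16 on day 30.

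Complement genes, whose products opsonise particles, climbed over the whole course. Their median change was 0.28 on day 1, 1.09 on day 3, 1.23 on day 7, 1.53 on day 30 and 1.87 on day 90, when 18 of 19 rose (18 adjusted over the list alone; camera adjusted p = 8.35e-16, and 0.00657 with an estimated correlation). The call of day 1 (camera adjusted p = 0.0179) was lost, at adjusted p = 0.38 with an estimated correlation. Cfi, the complement factor I protease, rose by 3.93 ± 0.14 on day 90 (adjusted p = 1.93e-28; chromosome 2, 227324985 to 227325044). Acute-phase and opsonin genes had a median of 0.30, 1.02, 1.25, 1.15 and 1.38 over the 5 days, with 14 of 16 higher on day 90 (15 adjusted over the list alone; camera adjusted p = 1.43e-11, and 0.00657 with an estimated correlation). Lysosomal and foreign-body macrophage genes had a median of 0.29, 0.40, 0.90, 1.18 and 1.35 over the 5 days, and 24 of 26 rose on day 90 (24 adjusted over the list alone; camera adjusted p = 1.38e-20, and 0.0218 with an estimated correlation). Atp6v0d2, a proton pump subunit of fused macrophages and osteoclasts, rose by 5.43 ± 0.23 on day 30. MHC class II genes, which present antigen, reached a median of 1.23 on day 90 with 10 of 11 higher (10 adjusted over the list alone; adjusted p = 0.0424 with an estimated correlation). Interferon response genes changed abruptly: on day 1 the median was −0.06, and on day 3 all 21 rose (21 adjusted over the list alone), by a median of 1.31 (camera adjusted p = 7.15e-18, and 0.0383 with an estimated correlation). They stayed higher to day 90 (median 0.87; 15 of 21, 15 adjusted over the list alone; camera adjusted p = 1.92e-05), although not at adjusted p = 0.293 with an estimated correlation. Cell cycle genes had a median of 1.27 on day 1, when 31 of 33 rose (31 adjusted over the list alone; adjusted p = 0.0205 with an estimated correlation), 1.49 on day 7 and 0.98 on day 90 (camera adjusted p = 2.43e-08; adjusted p = 0.15 with an estimated correlation).

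Some lists of the lung's own cells moved the other way, but not all. All 17 endothelial markers fell on days 30 and 90 (17 adjusted over the list alone), by a median of −0.88 and −0.95 (camera adjusted p = 6.37e-10 on day 90, and 0.00805 with an estimated correlation). Kdr, the receptor of vascular endothelial growth factor, fell by 1.12 ± 0.11 on day 30. All 12 markers of alveolar type 1 cells, the thin cells of gas exchange, fell on day 90 (12 adjusted over the list alone; median −0.73; camera adjusted p = 3.42e-07, and 0.0205 with an estimated correlation), Cav1 among them by 1.48 ± 0.13. Club cell markers of the bronchioles had a median of −0.69 on day 1, with 10 of 12 lower (10 adjusted over the list alone; adjusted p = 0.022 with an estimated correlation), and Cyp2f4 fell by 2.03 ± 0.13. Markers of type 2 cells, which make surfactant, went up instead on day 90, with a median of 0.60 and 9 of 16 higher and 1 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.00609, adjusted p = 0.237 with an estimated correlation). Collagen and matrix genes had a median of −0.42 on day 30 and −0.40 on day 90, when 2 rose and 16 fell of 28 (2 and 16 adjusted over the list alone; camera adjusted p = 0.00281, adjusted p = 0.268 with an estimated correlation). Cardiac muscle genes, which rat lungs carry in the walls of pulmonary veins, had a median of −1.34 on day 90, with 13 of 15 lower (13 adjusted over the list alone; camera adjusted p = 1.02e-06, adjusted p = 0.238 with an estimated correlation).

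In all, CNT-1 changed 6681 genes on day 1 (3111 higher, 3570 lower), 4829 on day 3 (2807 and 2022), 5641 on day 7 (3383 and 2258), 6665 on day 30 (3299 and 3366) and 6819 on day 90 (3569 and 3250), as the plot of counts by day shows. At least 2-fold were 1156, 700, 900, 1391 and 1533 of them, and 1080 genes were higher and 760 lower on all 5 days. Every array of 1 group lay beyond every array of the other in 4338, 5226, 6712, 7858 and 8019 genes, where chance gives 2.86% of genes. With the spread taken from the 12 arrays of day 1 alone, the count of day 1 was 2639. Normexp correction moved the split of day 1 to 2858 higher and 4694 lower. Centring arrays on their median moved the split of day 7 to 3935 higher and 1594 lower. The splits of days 30 and 90 were near even. The majority of day 30 turned with normexp correction (3389 higher, 3166 lower) and with the authors' tables (3367 and 3285). That of day 90 turned with quantile normalization (3365 and 3492).

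**Figure D2:**
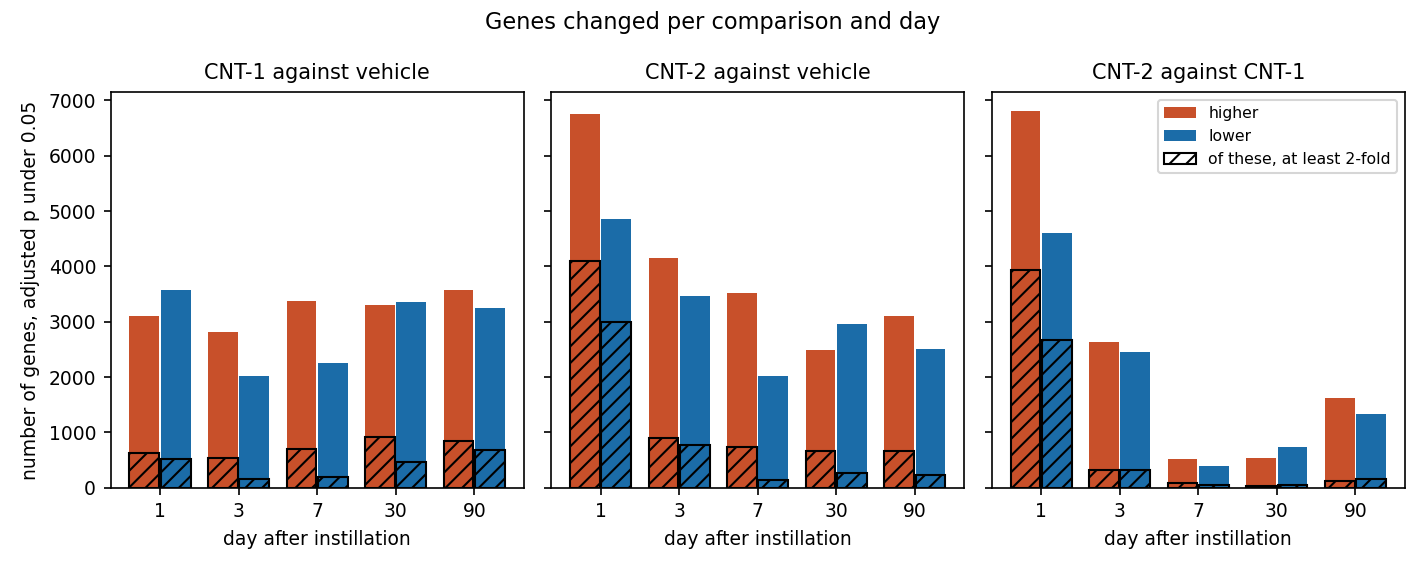
Bars give the number of genes higher (orange) and lower (blue) at an adjusted p under 0.05 in each comparison (panels) by day after instillation, with hatched parts for changes of at least 2-fold. CNT-2 lungs differed from vehicle in 11613 genes on day 1 and in 5462 to 7623 on later days, and from CNT-1 lungs in 913 genes on day 7. Slide and group cannot be told apart.

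CNT-2 against vehicle asks the same of the other material. Spp1 rose by 6.94 ± 0.32 on day 1, by 10.58 ± 0.32 on day 3 (1531-fold; adjusted p = 7.49e-31), by 9.82 on day 7, 8.02 on day 30 and 8.05 on day 90. Mmp7 was 45-fold higher on day 1, 416-fold on day 3, 803-fold on day 7, at least 362-fold higher on day 30, and 217-fold higher on day 90 (chromosome 8, 4533647 to 4533706). Mmp12 rose by 7.01 ± 0.21 on day 3, 7.25 ± 0.21 on day 7 (152-fold; adjusted p = 1.17e-31; chromosome 8, 4259057 to 4259413), 6.30 on day 30 and 6.16 on day 90. Il24 was 452-fold higher on day 1 (8.82 ± 0.30; chromosome 13, 43831514 to 43831573), 236-fold on day 3 and 48.4-fold on day 7. Atp6v0d2 rose by 6.32 ± 0.23 on day 7 and Retnla by 6.52 ± 0.31 on day 3 and 5.96 ± 0.31 on day 30. Cxcl11 was at least 68.9-fold higher on day 30. On day 90, when 1 vehicle array lay well above background, it was 53.6-fold higher. Falls from day 3 on were smaller: Serpinb10, a serpin of leukocytes, fell by 2.41 ± 0.19 on day 3, and Efnb1, the guidance ligand ephrin B1, by 2.71 ± 0.20 on day 90 (adjusted p = 4.48e-16). Kcns2, a potassium channel subunit, was at least 14.3-fold lower on day 7 and fell by 2.92 ± 0.57 on day 90. Between the vehicle groups of days 3 to 90, Efnb1 itself ranged by 2.13 and Kcns2 by 3.46, and Kcns2 was higher in vehicle on days 7 and 90, at −2.95 and −2.44, than on days 3 and 30, at −4.72 and −5.90.

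Day 1 of CNT-2 differed in scale from every other comparison with vehicle. Scd, the fatty acid desaturase of surfactant lipid synthesis, fell by 5.89 ± 0.44 (adjusted p = 2.68e-17), and Cav1, the caveolin of type 1 and endothelial cells, fell by 4.16 ± 0.13 (adjusted p = 1.03e-31). Cav2, its partner, fell by 6.77 ± 0.57, and Sox17, an endothelial transcription factor, by 4.01 ± 0.25. Fosl1, a subunit of the AP-1 transcription factor, rose by 5.19 ± 0.24 and Cxcl2 by 4.57 ± 0.18, and Timp1, an inhibitor of metalloproteinases, by 4.03 ± 0.11 (adjusted p = 4.46e-33). CNT-2 lungs differed from vehicle in 11613 of the 13559 genes (6753 higher, 4860 lower), 7101 of them at least 2-fold. The median of all genes moved by 0.28. The sign of that shift depended on the scaling: with quantile normalization the median was −0.17 and the split 5084 higher and 6428 lower, and with arrays centred on their median −0.27 and 4629 higher and 6605 lower. With normexp background correction the median was 0.40. Different probes of a gene also differed here: the correlation between the changes of 2 probes, over 3388 genes, was 0.28, against 0.46 for CNT-1 on day 1 and 0.69 to 0.86 in the other comparisons with vehicle. Csf1r, the receptor of the macrophage growth factor CSF1, for example, fell by 1.84 on its brightest probe and rose by 4.37 on another. Of the lists, neutrophil markers had a median of 2.17, with 9 of 13 higher (9 adjusted over the list alone; camera adjusted p = 0.0224, adjusted p = 0.279 with an estimated correlation).

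Lysosomal and foreign-body macrophage genes, which digest engulfed material, were higher under CNT-2 from day 3 to day 90. Their median change was 1.41, 1.35, 1.23 and 1.21 on days 3, 7, 30 and 90, with 23, 25, 23 and 24 of 26 higher (24, 25, 24 and 24 adjusted over the list alone; camera adjusted p = 3.6e-31 on day 30, and 0.019 with an estimated correlation). Complement genes reached a median of 1.52 on day 90, with 17 of 19 higher (18 adjusted over the list alone; camera adjusted p = 4.59e-16, and 0.019 with an estimated correlation). Acute-phase and opsonin genes had a median of 1.21 on day 3 and 0.98 on day 90, with 15 of 16 higher (15 adjusted over the list alone; adjusted p = 0.019 with an estimated correlation). Neutrophil markers, in contrast to day 1, had medians of 0.54, 0.82, 0.68 and 0.63, and 8 of 13 were higher on day 90 (9 adjusted over the list alone; camera adjusted p = 0.000933, adjusted p = 0.0948 with an estimated correlation). Interferon response genes had a median of −0.20 on day 3, 0.80 on day 7, 1.04 on day 30 and 0.94 on day 90, with 16 of 21 higher on the last (17 adjusted over the list alone; camera adjusted p = 9.25e-08, adjusted p = 0.223 with an estimated correlation). Cell cycle genes peaked on day 3, with 32 of 33 higher (32 adjusted over the list alone) and a median of 1.91 (camera adjusted p = 4.96e-18, and 0.0409 with an estimated correlation). Alveolar macrophage markers, those of the resident phagocytes, had a median of 0.83 on day 90, with 7 of 10 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0471 with an estimated correlation).

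Markers of several cell types fell under CNT-2 as well. All 17 endothelial markers were lower on days 3 and 30 (17 adjusted over the list alone), by a median of −1.02 and −0.75 (camera adjusted p = 4.96e-09 on both, and 0.019 with an estimated correlation). By day 90 the median was −0.51 and 12 were lower (12 adjusted over the list alone; camera adjusted p = 4.71e-05, adjusted p = 0.0855 with an estimated correlation). All 12 type 1 cell markers fell on day 30 (12 adjusted over the list alone; median −0.48; adjusted p = 0.0498 with an estimated correlation). Type 2 cell markers rose on day 90, by a median of 0.53, with 11 of 16 higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.00362, adjusted p = 0.223 with an estimated correlation). Of 15 cardiac muscle genes, 13 were lower on day 30 (14 adjusted over the list alone; median −1.03; camera adjusted p = 5.49e-06, adjusted p = 0.295 with an estimated correlation). On the same day 13 of 15 ciliated cell markers (14 adjusted over the list alone; median −0.58; camera adjusted p = 4.73e-05, adjusted p = 0.17 with an estimated correlation) and 5 of 7 erythrocyte genes were lower (6 adjusted over the list alone; median −0.90; camera adjusted p = 0.0372, adjusted p = 0.381 with an estimated correlation). On day 3 the medians of these 3 lists were −1.1, −0.70 and −1.26, with 12, 12 and 6 genes lower (13, 12 and 6 adjusted over the list alone). Of 15 circadian clock genes, 8 were higher and 3 lower on day 90 (8 and 3 adjusted over the list alone; median 0.80), but the list did not pass camera (adjusted p = 0.0581, and 0.0972 with an estimated correlation). Dbp, an output gene of the clock, rose by 2.98 ± 0.20 on day 90 (adjusted p = 3.73e-17; chromosome 1, 96178020 to 96178079), and Bmal1, a core activator of the clock, fell by 1.26 ± 0.10 (adjusted p = 2.43e-14). CNT-2 changed 7623 genes on day 3 (4159 higher, 3464 lower), 5540 on day 7 (3511 and 2029), 5462 on day 30 (2498 and 2964) and 5606 on day 90 (3100 and 2506). Quantile normalization turned the split of day 3, to 3633 higher and 3911 lower. At least 2-fold were 1678, 876, 919 and 895 of them, and 937 genes were higher and 471 lower on all 5 days. The split of day 1 turned with the scaling, and these tallies were not computed under other scalings. On days 3 to 90, without day 1, 1398 genes were higher and 929 lower on every day. Groups did not overlap in 9980, 7659, 6139, 7492 and 7721 genes on days 1 to 90, against a chance share of 2.86%.

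**Figure D3:**
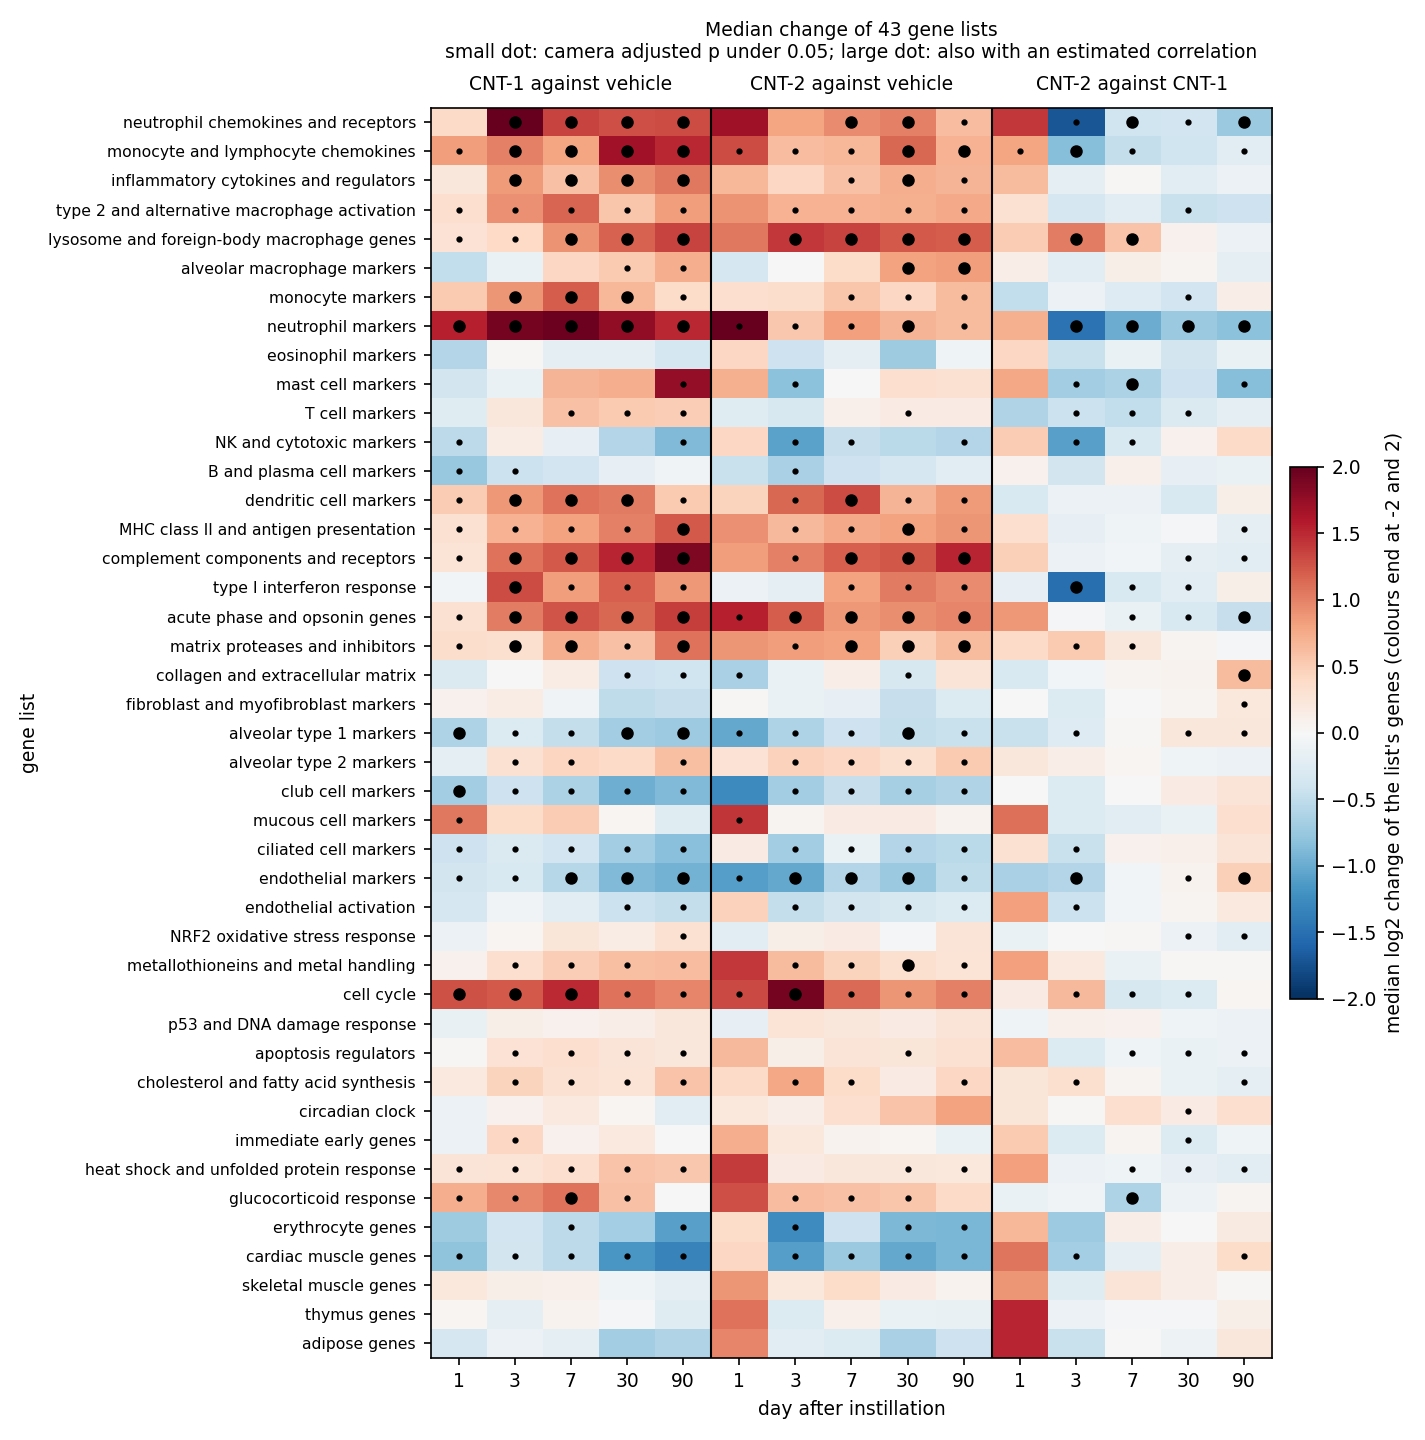
Each cell gives the median log2 change of 1 of 43 gene lists (vertical) in a comparison and day (horizontal, days after instillation), from blue (lower) to red (higher), with a small dot for camera's adjusted p under 0.05 and a large dot where the estimated correlation kept the call. Neutrophil markers under CNT-1 stay between 1.5 and 1.96, and complement genes rise from 0.28 on day 1 to 1.87 on day 90.

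The comparisons of both materials with vehicle asked how much of the response was shared. Spp1 was higher in all 10 comparisons with vehicle. In total 90 genes were at least 2-fold higher in all 10 and 1 gene at least 2-fold lower. These counts include CNT-2 on day 1, where the split depended on the scaling. Across genes, which are not independent replicates, the correlation of the CNT-1 and CNT-2 changes was 0.56, 0.72, 0.86, 0.91 and 0.84 on days 1, 3, 7, 30 and 90. Without array 1 of CNT-1 day 1, the value of day 1 was 0.38. Unchanged groups simulated against the same vehicle arrays gave 0.50 on each day, because the arrays of the vehicle enter both changes. With the vehicle arrays split between the materials, the correlation averaged 0.53, 0.64, 0.78, 0.85 and 0.79. Both parts of the split lie on 1 slide, so a shift of that slide would still enter both changes. The simulation holds no effect of a slide. The covariance was 0.546, 0.276, 0.296, 0.366 and 0.346, against 0.0379, 0.0191, 0.0169, 0.0124 and 0.0117 in the simulation. On day 30, 2262 genes were higher in both and 2448 lower in both, where independent lists would share 608 and 736. There, 5 genes went opposite ways, where independent lists would give 1341. On day 1, 2256 genes were higher in both, 2113 lower in both and 1516 opposite. Independent lists would give 1549, 1280 and 2893. The split of the CNT-2 calls of day 1 turned with quantile normalization and with array medians. These shared counts were not computed under those scalings. In simulated data sets where no gene changed, both materials shared at most 1 call. Few calls arise there at all, so this does not show how many shared calls come from the vehicle arrays.

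CNT-2 against CNT-1 asks where the materials differed. Lysosomal and foreign-body macrophage genes were higher under CNT-2 on days 3 and 7 and neutrophil markers lower, and interferon response genes were lower on day 3. On day 3, Spp1 was higher by 5.44 ± 0.32 (43.5-fold; adjusted p = 1.33e-18), Il24 by 4.43 ± 0.30 and Pla2g10, a secreted phospholipase, by 4.37 ± 0.16 (adjusted p = 1e-26). Nos2, the inducible nitric oxide synthase, was 11.6-fold lower (−3.53 ± 0.26), Orm1 10.5-fold and Ifit3, an interferon-induced gene, 8.67-fold. On day 7, Mt3, a metallothionein that binds zinc and copper, was 26.5-fold higher (4.73 ± 0.22; adjusted p = 2.92e-22; chromosome 19, 11284638 to 11284697), and S100a9 and S100a8, the subunits of calprotectin, were 8.28- and 7.5-fold lower (adjusted p = 1.53e-15 and 5.77e-16). Both stayed lower on day 30, at 4.93- and 5.59-fold. Lpo was 9.22-, 9.51- and 31.6-fold lower on days 7, 30 and 90 (adjusted p = 8.43e-18 on day 90; chromosome 10, 76102064 to 76102123). Orm1 was 9.13-, 5.72- and 30.1-fold lower. Of 15 circadian clock genes, 7 were higher and 4 lower on day 90 (7 and 4 adjusted over the list alone; median 0.33), and the list did not pass camera (adjusted p = 0.0741, and 0.155 with an estimated correlation). Dbp was higher by 2.26 ± 0.20 on day 30 and 2.38 ± 0.20 on day 90. Nr1d1, a repressor within the clock, was higher by 2.82 ± 0.35 on day 90 (adjusted p = 2.28e-08; chromosome 10, 87543165 to 87543519). Esr1, the estrogen receptor alpha, was 9.06-fold lower on day 90.

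The lists bore the same contrast. Of 13 neutrophil markers, 8 were lower on each of days 3, 7, 30 and 90 (8, 9, 10 and 10 adjusted over the list alone), and 2 were higher on day 3 (2 adjusted over the list alone), with medians of −1.48, −0.99, −0.75 and −0.82 (camera adjusted p = 2.92e-19 on day 7, and 0.0472, 8.59e-05, 0.000781 and 0.00253 with an estimated correlation). All 21 interferon response genes were lower on day 3 (21 adjusted over the list alone), by a median of −1.51 (camera adjusted p = 2.23e-22, and 0.0472 with an estimated correlation). On day 90 the median was 0.11 and no gene of the list differed (0 adjusted over the list alone). Lysosomal and foreign-body macrophage genes were higher on days 3 and 7, by a median of 1.03 and 0.57, with 24 and 20 of 26 higher (24 and 22 adjusted over the list alone; adjusted p = 0.0342 and 0.017 with an estimated correlation). Cytotoxic and natural killer cell markers were all lower on day 3, 11 of 11 (11 adjusted over the list alone; median −1.09; camera adjusted p = 2.07e-08, adjusted p = 0.0686 with an estimated correlation). Collagen and matrix genes, the scaffold of the lung wall, were higher on day 90, with 21 of 28 higher and none lower (21 adjusted over the list alone; median 0.63; camera adjusted p = 3e-12, and 0.0339 with an estimated correlation). Endothelial markers were lower on day 3 (median −0.58; 14 of 17, 15 adjusted over the list alone) and higher on day 90 (median 0.48; 12 of 17, 16 adjusted over the list alone; adjusted p = 0.0436 and 0.0339 with an estimated correlation). Glucocorticoid response genes were lower on day 7, by a median of −0.62, with 5 of 13 lower (8 adjusted over the list alone; adjusted p = 0.0339 with an estimated correlation). On day 1 only the monocyte and lymphocyte chemokines passed camera, with 18 of 21 higher (18 adjusted over the list alone; camera adjusted p = 0.0492), and the call was lost at adjusted p = 0.609 with an estimated correlation.

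Between the materials, 11412 genes differed on day 1 (6810 higher under CNT-2, 4602 lower), 5103 on day 3 (2643 and 2460), 913 on day 7 (515 and 398), 1267 on day 30 (538 and 729) and 2964 on day 90 (1630 and 1334). At least 2-fold were 6610, 648, 151, 93 and 294 of them. With the spread taken from the arrays of the day alone, more genes passed on days 7, 30 and 90, at 1377, 3575 and 5789. The groups did not overlap in 8558, 5581, 2676, 3505 and 5249 genes (chance 2.86%). Scaling moved several of these splits. On day 1 the median of all genes was 0.32, with 5065 higher and 6193 lower after quantile normalization (median −0.13), 4529 and 6398 after centring on the median (−0.22), and 8195 and 3533 after normexp correction (0.52). Quantile normalization turned the split of day 3, to 2225 and 2716. Normexp gave 977 and 433 on day 7, and centring gave 310 and 522 on day 7, 500 and 428 on day 30, and 941 and 1799 on day 90. The count of day 30 was 709, 745 and 755 without array 1, 3 or 4 of CNT-1 day 30, and 787 without array 3 of CNT-2 day 30. On days 7 and 90 both materials were scanned on the same day, so the differences given for those days lie within 1 scan day.

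**Figure D4:**
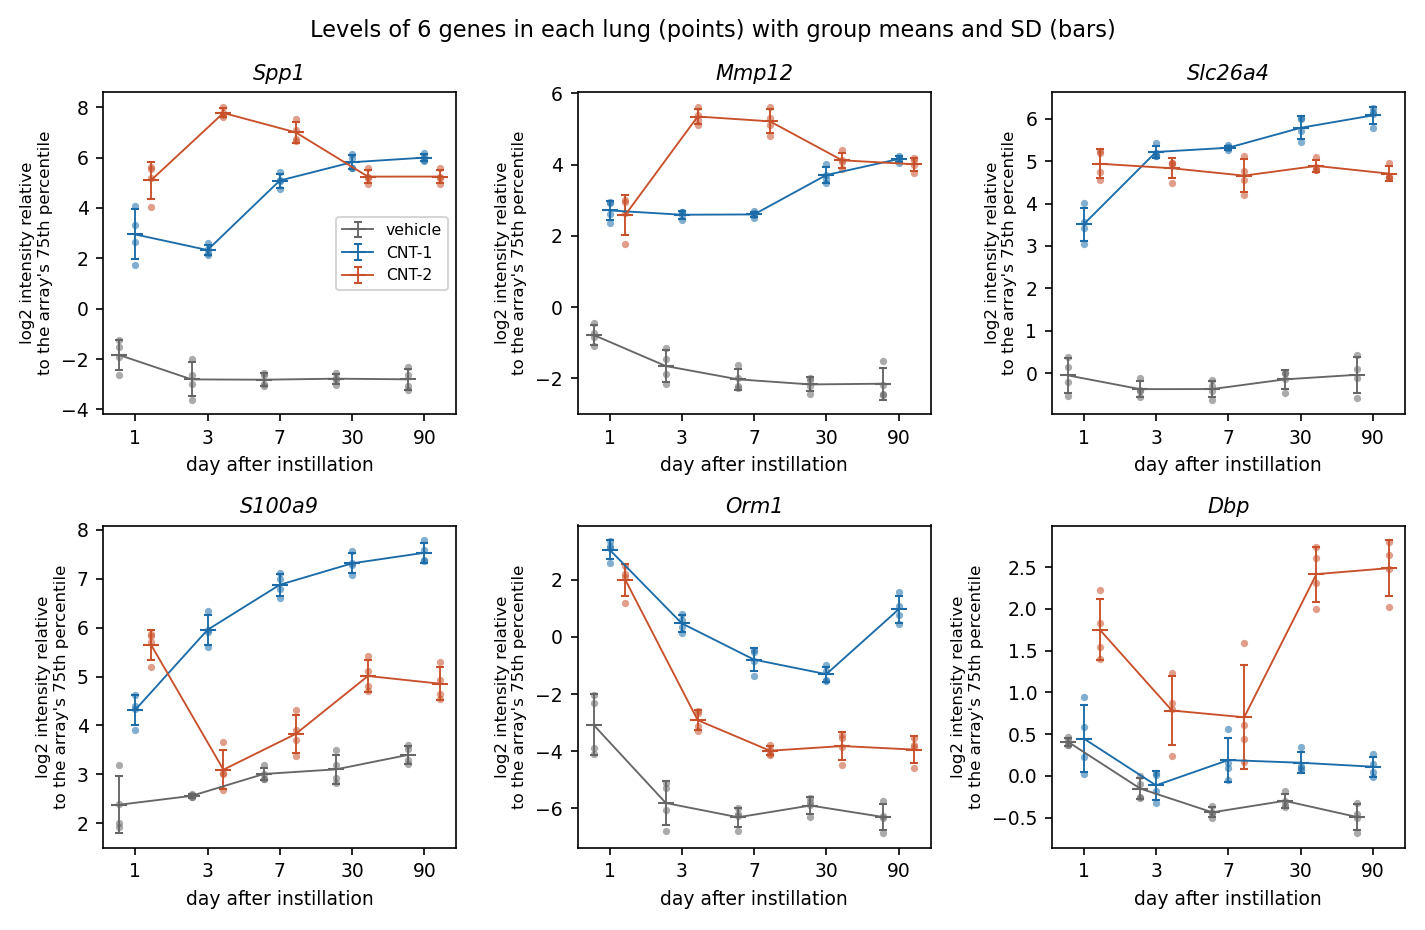
Points give the level of 6 genes (log2 intensity relative to the array's 75th percentile, vertical) in each lung by day after instillation (horizontal), with group means joined by lines and bars for the SD of 4 lungs, for vehicle (grey), CNT-1 (blue) and CNT-2 (orange). On day 3, Spp1 averages 7.77 under CNT-2, 2.33 under CNT-1 and −2.81 in vehicle, and on day 7 S100a9 averages 6.88 under CNT-1 and 3.83 under CNT-2.

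Whether the effect of a material changed between day 1 and day 90 was tested as the difference of its effects on both days. For CNT-1, Mt3 gained 4.62 ± 0.31 (adjusted p = 8.1e-17) and Sctr, the secretin receptor gene, 4.83 ± 0.48, each toward higher on day 90. Efnb1 had a difference of −4.81 ± 0.28 (adjusted p = 6.29e-19) and Rnase11, a member of the ribonuclease A family, of −6.10 ± 0.82. Their level also ranged between the vehicle groups of days 3 to 90, by 2.13 for Efnb1 and 3.13 for Rnase11. In all, the CNT-1 effect differed for 5018 genes, 2742 of them toward higher on day 90. For CNT-2, the effect differed for 10904 genes (4769 toward higher, 6135 toward lower), with a median over all genes of −0.23 that became 0.20 after quantile normalization (6179 and 4746) and 0.29 after centring on the median (6283 and 4262). Cybb, which encodes the phagocyte oxidase subunit NOX2, had a difference of 7.07 ± 0.80 (adjusted p = 4.52e-11), Tspan12, a membrane organiser of endothelial signalling, of 6.38 ± 0.86, and Bccip, a DNA repair gene, of −5.87 ± 0.22 (adjusted p = 4.77e-27). These CNT-2 differences use the slide of CNT-2 day 1, which was dim (75th percentile 8.49) and whose probes disagreed within genes (correlation 0.28). Those of CNT-1 use CNT-1 day 1, where that correlation was 0.46 and array 1 was dim (75th percentile 9.31, against 10.65 to 10.86 on the others). The CNT-1 count was 3367 with the spread of the arrays of days 1 and 90 alone, and 5433 without that array. An alternative chosen after seeing the data took day 3 in place of day 1. With it, the effects of CNT-1 and CNT-2 on day 90 differed for 2309 and 3862 genes. Of the values of genes named for the interactions, 8 stayed the same, 6 fell below the threshold and 2 reversed.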

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

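The test of a CNT-1 array against the CNT-2 changes of day 1 was chosen after the result was seen. Single arrays far from the other 3 of their group were looked for in 856 pairs of a named gene and a group, and 52 pairs (6.1%) had one, where chance gives about 1 in 20. Array 1 of CNT-1 day 1 lay apart in 10 named genes (Rchy1, Cdc42ep3, Zfp608, Magea9, Sgms1, Cog6, Kcns2, Clec10a, Npas2 and Fabp4), and array 3 of vehicle day 1 in 5 (Tspan12, Cav2, Fabp4, Saa4 and Agr3). Array 2 of CNT-2 day 1, array 2 of vehicle day 30 and array 1 of vehicle day 90 lay apart in 3 genes each. Arrays 1, 2 and 3 of CNT-1 day 30, array 2 of CNT-1 day 90 and arrays 3 and 4 of vehicle day 90 did so in 2 each, and 16 further arrays in 1 gene each.

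The same rule was applied to 8 measures of each array in each group, 120 tests in all, of which chance again gives about 1 in 20. Array 1 of CNT-1 day 1 had a 75th percentile of 9.31 (log2 intensity) against 10.65, 10.86 and 10.81 on the others, a mean correlation with its group of 0.9469, and 18.3% of its signal in the 100 brightest spots. The 75th percentile was also low on array 2 of vehicle day 3, at 9.99, and on array 2 of CNT-1 day 3, at 9.74, where the brightest spots held 18.5%. That share was 26.4% on array 2 of CNT-2 day 1, with a spike-in slope of 1.075, and 18.7% on array 2 of CNT-1 day 30. Array 4 of vehicle day 1 had 62.3% of spots well above background, array 1 of CNT-2 day 3 a mean correlation of 0.9936, array 4 of CNT-1 day 7 an interquartile range of 3.45, and array 1 of CNT-1 day 90 a spike-in slope of 0.9994.

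The effect of a material differed between day 90 and day 1, by the test of the difference itself, for 5018 genes under CNT-1 and 10904 under CNT-2. Of 100 splits that reassigned the arrays within each day, 3 gave as many genes for CNT-1, the real one included, with 6105 the highest of the others. For CNT-2 the real split, 1 of 100, gave the most, with 10352 the highest of the others. Such splits mix material and vehicle on both days, so they stand for no effect on either day and not for equal effects. They cannot show whether the effect differs between the days.

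For the 15 comparisons by day, the real split was the 1 of 35 with the most genes in each, the smallest share these splits can give. A random assignment of the arrays was thus argued against. The real split is also the split between slides, so this cannot tell a material from its slide. The highest of the other splits gave 4286, 1124, 1236, 2676 and 1741 genes for CNT-1 on days 1 to 90, against 6681, 4829, 5641, 6665 and 6819 in the real split. For CNT-2 they gave 9299, 3369, 1552, 1015 and 1183, against 11613, 7623, 5540, 5462 and 5606. Between the materials they gave 9689, 781, 51, 9 and 253, against 11412, 5103, 913, 1267 and 2964.

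On day 1 most genes differed between CNT-2 and vehicle, and the changes differed from those of all later days. Their correlation across genes with later days was 0.08 to 0.25, against 0.63 to 0.82 among the later days. For CNT-1 the values were 0.33 to 0.51 and 0.69 to 0.86, a gap of the same direction. For CNT-2 on day 1, a change of RNA levels that every probe of a gene reads alike was argued against as the whole cause. The changes of 2 probes of a gene correlated at 0.28, below the lowest of the other 9 comparisons with vehicle, 0.46. Array quality is a candidate explanation that would not need CNT-2: array 1 of CNT-1 day 1, the dimmest of its group, deviated from the other 3 along the CNT-2 day 1 changes, with a correlation across genes of 0.59 (0.01 to 0.07 with the CNT-2 changes of later days, and 0.04, −0.21 and 0.13 for the other 3 arrays). Shortened or poorly copied RNA stayed open. The probe farther upstream changed by −0.22 against the probe downstream, between the bounds set for and against this explanation. That median is over 3064 genes (95% bootstrap interval −0.30 to −0.13), and the interval leaves out the spread between slides. In the other comparisons with vehicle it ran from −0.05 (CNT-2 day 30) to 0.16 (CNT-2 day 90). The upstream probe was lower in 54.7% of genes for CNT-2 on day 1 and in 25.7% on day 90. Between the materials the median was −0.11 on day 30 and 0.14 on day 90, with 70.1% and 27% lower. The position of the probe thus entered other comparisons too, and why was not tested. An effect of CNT-2 on day 1 stayed open as well, and cannot be told apart from the slide, because the group filled 1 slide of its own.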

How the results depend on the processing

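The fits without the day 1 arrays, without the CNT-2 day 1 arrays and with day 3 in place of day 1 were chosen after the result was seen. Over 16 other settings, 6287 of 6344 values of named genes stayed the same, 50 fell below the threshold and 7 reversed. The same meant an unchanged direction and side of the threshold. The deposited series table (444 values) allows no test, so there it meant a value within the gene's SD. The genes were chosen for large or significant changes, and settings that alter only the test cannot reverse them. Over 13 settings, 7737 of 8170 list shifts kept direction and side of the threshold, with 341 lost, 90 gained and 2 reversed. Where no other value is given here, counts of genes stayed within 1.5 times those reported, for example 5046 to 8626 for CNT-1 on day 1 and 4205 to 7994 on day 7.

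Normexp correction gave 1410 genes between the materials on day 7 and a correlation of 0.93 on day 30. Quantile normalization reversed Ptcra under CNT-2 on day 1 (−0.11 against 0.52) and the alveolar type 2 markers on day 1, against vehicle (median −1.03 against 0.29) and against CNT-1 (−1.12 against 0.23). Array medians reversed Ptcra (−0.03) and Prg2 (−0.13 against 0.42) under CNT-2 on day 1. Both scalings also moved the median of all genes there, from 0.28 to −0.17 and −0.27. The mean of all probes reversed Csf1r (1.27 against −1.84) and Ryr2 (0.11 against −1.89) under CNT-2 on day 1, since their probes differ in direction. Without the filter, correlations were 0.68, 0.78, 0.87 and 0.81 on days 3, 7, 30 and 90. With vehicle arrays split between the materials they were 0.64, 0.78, 0.85 and 0.79. No vehicle array then enters both changes, but fewer arrays enter each, and what lowered the values was not tested.

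Array weights gave 8623 and 8644 genes for CNT-2 on days 30 and 90, 3204, 5271 and 7169 between the materials on days 7, 30 and 90, and 8101 for the CNT-1 interaction. The arrays of the day alone gave 2639 for CNT-1 on day 1, and 1377, 3575 and 5789 between the materials on days 7, 30 and 90. Without the day 1 arrays the latter were 2124, 3305 and 5179. Those 2 fits leave the log2 changes of a comparison as they are, so only the estimate of the spread and its degrees of freedom moved the counts. The cause was not tested for array weights, normexp and the filter. Without the CNT-2 day 1 arrays, the 14 counts of genes that do not use them stayed within 1.5 times.

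At least 2-fold were 1156, 700, 900, 1391 and 1533 genes for CNT-1, 7101, 1678, 876, 919 and 895 for CNT-2, 6610, 648, 151, 93 and 294 between the materials, and 1594 for the CNT-1 interaction. At an adjusted p under 0.01, counts between the materials were 498, 540 and 1813 on days 7, 30 and 90. These settings pass fewer genes by construction. An estimated correlation called 97 lists in place of 310. With day 3 in place of day 1, interactions were 2309 and 3862 genes, and Appbp2 (−0.36 against 6.50) and Or8b52 (0.61 against −5.58) reversed for CNT-2, where another day is compared.

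Leaving out each array in turn, 3676 of 3680 values of named genes and 5005 of 5160 list shifts stayed as they were, 4 genes and 87 lists fell below the threshold, and 68 lists passed it. Between the materials on day 30 the count ran from 709 without CNT-1 day 30 replicate 1 to 1559 without replicate 2. It was 745 and 755 without CNT-1 day 30 replicates 3 and 4, and 787 without CNT-2 day 30 replicate 3. The correlation of day 1 ran from 0.38 without CNT-1 day 1 replicate 1 to 0.60 without replicate 3, and that of day 30 from 0.89 without CNT-1 day 30 replicate 2 to 0.91. The cause was not tested.

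With the number of the array as a replicate block, counts moved by 0.90 to 1 times, to 1135 between the materials on day 30 and 874 on day 7. Arrays with the same number share only a number: their deviations from the group means correlated at 0.01 on average over 60 pairs, with −0.18 the lowest, and 0 of 15 pairs of groups had every correlation over 0.1. Blocking changed no call of a named gene, gained 2 lists and lost 4. The slide or the scan day as a block was not run, since each group filled 1 slide and the scan day leaves comparisons within it as they are. Signal over background limits what can be seen of dim genes.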

Other observations

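Both tests of the clock genes and the test of a steady course were chosen after the result was seen. Of the lists that the report does not describe for CNT-1, ciliated cell markers had a median of −0.83 on day 90, with 1 of 15 higher and 13 lower (1 and 13 adjusted over the list alone; camera adjusted p = 0.000102, and 0.167 with an estimated correlation). Erythrocyte genes had a median of −1.09, with 6 of 7 lower (6 adjusted over the list alone; camera adjusted p = 0.016, and 0.284), and NRF2 target genes of 0.31, with 11 of 25 higher and 4 lower (11 and 5 adjusted over the list alone; camera adjusted p = 0.0311, and 0.167).

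Between CNT-2 and CNT-1, 6 of 8 output genes of the clock were higher on each of days 30 and 90 (median 1.13 and 1.57), with 1 lower on day 90 (Bhlhe41, −0.41), and 3 of 5 genes in phase with Bmal1 were lower and 0 higher (median −0.63 and −0.75). The medians of both phases lay −0.39, 0.85, 0.74, 1.76 and 2.31 apart on days 1, 3, 7, 30 and 90, with opposite signs on each day. An effect of the slide that ignores gene function was argued against, because the smaller of the distances on days 30 and 90 was 1.76, with opposite signs on both. Different clock times of dissection may explain the pattern and stay open: the phase difference ranged by 0.69 over the 5 vehicle groups, against 2 between CNT-2 and CNT-1 on day 90, but vehicle groups dissected at a single time would give this too. The labels give no time of day, and an effect of CNT-2 on the clock was not tested apart from this.

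Vehicle groups themselves differed. Between days 3 and 90, 50 genes lay at least 4-fold apart between vehicle groups, and 8 of the 67 genes named for the largest changes are among them, Efnb1, Kcns2 and Rnase11 of the report included. They were highest in vehicle on day 3 for 11 genes, on day 7 for 18, on day 30 for 3 and on day 90 for 18. A steady course with age was argued against for most of these genes, because 14% rose or fell steadily. That is 7 of 50 (exact 95% interval 5.82% to 26.7%), where chance gives 8.3%. The interval takes genes as independent, though all rest on the same vehicle groups, so it leaves out the spread between rats and slides. Measurement by single probes on a slide could not be decided, since 1 gene had a second probe, which showed 0.43 of the change.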
